A study of Mus musculus with 18 samples.

How the data were processed

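Gene expression was measured by RNA sequencing in 18 libraries of primary mouse preadipocytes, in 6 groups of 3 libraries given by genotype label (WT or KO) and day of adipogenic differentiation (0, 2 or 8). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was prepared with Qiazol and a column kit, and libraries were made with a directional NEBNext kit. Per the submitters' processing notes, reads were counted per gene with featureCounts 1.5.2 on the mouse build mm10 (GRCm38). The aligner, the annotation release, the strand setting of the counting and the formula behind the values were not given in the sources used here. Genes that overlap another gene, lie antisense to one or share reads with a close paralog are therefore uncertain.

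The values were TPM (reads per gene relative to transcript length, rescaled to a fixed total per library) as the authors deposited them, in 1 table of 32828 genes. Each library summed to 1e+06 TPM. TPM keeps no record of the number of reads, so the depth of each library is unknown and no counting interval could be given. Because the total is fixed, a rise in a few abundant genes lowers all others, and the fold changes are relative to the rest of the transcriptome. Symbols missing from the table were filled from a reference table of gene names for 12574 genes, and 32790 identifiers were found there. Gene positions were taken from GENCODE vM21 on GRCm38, where 13066 of the tested identifiers were found. Shares of TPM from the mitochondrial chromosome were summed by gene type there, a step added after the data were seen.

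The tests were run on log2(TPM + 1), the 1 being the pseudocount, for the 13072 genes with a mean of at least 1 TPM over the 18 libraries. A fold change on this scale understates the change of genes with low TPM. One linear model with a coefficient per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Adjusted p-values are Benjamini-Hochberg values over the 13072 genes from two-sided tests, and a gene was called at an adjusted p below 0.05. The comparisons were KO against WT at each day, day 2 against day 0 and day 8 against day 2 within each genotype label, and the 3 interactions of label with day. Rictor was also compared by a two-sided exact permutation test on TPM, which cannot fall below 0.1 with 3 libraries against 3.

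Gene lists of pathways and cell types, 40 in all, were written from textbook knowledge before the data were examined, as were the groups, the tests above, the rule for naming genes and most of the alternatives. Of 754 list entries, 752 were found and 666 passed the filter. The 36 lists with at least 5 kept members were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The camera test was repeated with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance in 1 direction. Members were counted after adjustment over all genes and adjusted over the list alone. For day comparisons only the counts of members were used.

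Libraries with the same replicate number deviated together, which was checked before any calls were compared. The correlation (across genes) of deviations from the group means lay between 0.652 and 0.955 for the 9 pairs of WT and KO libraries of the same day and number, and between -0.825 and 0.383 for 18 pairs of the same day with different numbers. The labels do not say what a number shares, and the pairing rests on these values. Same-numbered libraries of different days correlated less, between -0.005 and 0.497 in 36 pairs, with 33 above 0.1. A limma fit with each day and number as a block (9 blocks, all 18 libraries) was therefore added after the data were seen, beside the block fits planned before, which used the number over all days or within a single day. It is called the blocked fit in the text, and the fit without a block is called the unblocked fit. The blocked fit pools the residual spread of the 3 days.

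Genes were named by a rule. Rictor was always named. In each comparison of labels, up to 10 genes with the largest positive and 10 with the largest negative change were named among called genes whose 3 values in 1 group all exceeded those of the other and whose higher group averaged at least 5 TPM, without predicted, clone-named or mitochondrial genes. For each list, up to 4 members with the smallest adjusted p were named, and, for a list that was not called, up to 3 members with the highest mean TPM. In each day comparison and interaction, up to 5 genes were named in each direction. A set of 12 adipocyte genes (Pparg, Cebpa, Adipoq, Fabp4, Plin1, Mlxipl, Srebf1, Fasn, Acly, Slc2a4, Lpl and Cd36) was followed in every comparison. Applying the rule to the blocked fit as well was decided after the data were seen.

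The procedure was tested on simulated data built on KO against WT at day 8, with 13072 genes of which 200 were changed. At a 2-fold change the unblocked fit recovered 68.5% and the blocked fit 94% of the changed genes. At a 1.5-fold change the shares were 10.5% and 75%. Unchanged genes were called 0 and 7 times in the unblocked and blocked fits at 2-fold, and 0 and 11 times at 1.5-fold. The simulated values held a shared deviation for each pair and the same residual spread of a gene on every day, independent between genes. These are the assumptions of the blocked fit, so the shares and false calls may not apply to the real day 8 comparison.

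Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, a fit to the compared groups alone, no intensity trend, sample quality weights, the block fits and leaving out each library in turn. Blocked fits with other scalings, with quality weights, and without the day 8 pair numbered 3 or the day 0 pair numbered 2, were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Lists of epithelial or mammary, mesothelial and skeletal muscle markers kept 2, 2 and 4 members and were not tested, and none of the 11 T or B cell markers passed the filter.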

Results

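The transcriptome was measured in 18 libraries of primary mouse preadipocytes, the fibroblast-like precursors of fat cells, grown from the stromal vascular fraction of subcutaneous fat. The cells carried loxP-flanked (floxed) alleles of Rictor and CreERT2, a Cre recombinase activated by 4-hydroxytamoxifen (4-OHT). Rictor encodes a subunit of mTOR complex 2 (mTORC2), a kinase complex that phosphorylates AKT downstream of insulin. Precursors received 4-OHT (libraries labelled KO) or ethanol (libraries labelled WT) and were then induced with insulin, dexamethasone, IBMX and rosiglitazone. RNA was taken at days 0, 2 and 8, with 3 libraries per genotype label and day. The comparisons asked how loss of Rictor altered gene expression before, early in and late in adipocyte differentiation. Each of them also compared 4-OHT with ethanol. The control genotype label reads as if Cre were absent, whereas the series design describes inducible Cre in the cells, and this was not resolved. Between 12495 and 13084 genes per library reached 1 TPM, and the 10 most abundant genes took 7.51% to 11.4% of TPM. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples.

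Rictor itself was higher, not lower, in the libraries labelled KO. The gene (ENSMUSG00000050310) lies on chromosome 15 from 6708379 to 6800401 on the plus strand of GRCm38. At day 0 its level was 59.5 ± 2.3 TPM in KO and 47.2 ± 5.28 TPM in WT (SD, n = 3), a ratio of 1.26. The ratio was 1.53 at day 2 (61 ± 2.29 against 40 ± 3.28 TPM) and 1.49 at day 8 (78.5 ± 5.39 against 52.7 ± 2.83 TPM). The library labelled KO held more Rictor in each of the 3 pairs at each day. Exact permutation tests gave p = 0.1 at each day, the smallest value possible with 3 against 3. The adjusted p in limma was 1, 0.343 and 0.216 at days 0, 2 and 8 without a block, and 0.107, 0.0194 and 0.00674 in the blocked fit. Deletion of a single exon need not lower a whole-gene TPM value, because the 38 coding exons of Rictor include no internal exon above 5.94% of its 16930 bp of exonic sequence. The floxed exon was not given in the sources used here. The value thus checks neither the deletion nor the labels, and since it goes against them the groups are called by their labels throughout. Every direction below is that of the libraries labelled KO relative to those labelled WT. Rptor and Mtor, which encode the raptor subunit of mTORC1 and the shared kinase, had log2 differences of -0.003 and 0.031 at day 8.

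**Figure D1:**
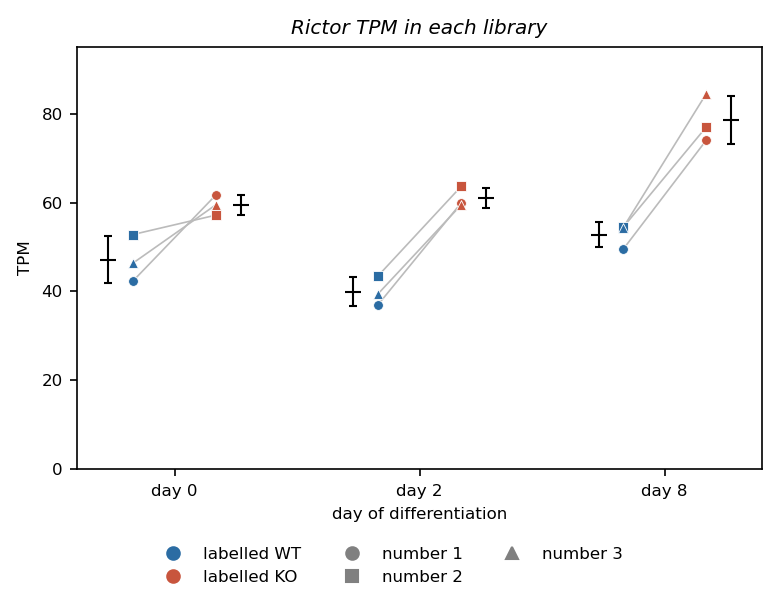
Rictor TPM (y axis) in each of the 18 libraries by day (x axis), with libraries labelled WT in blue and KO in red, marker shape for the replicate number, grey lines joining libraries of the same day and number, and black bars for the mean ± SD of 3 libraries. Group means were 47.2, 40 and 52.7 TPM in WT and 59.5, 61 and 78.5 TPM in KO.

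Differentiation was followed first within each label. Fold changes here and below are on the TPM + 1 scale and are not ratios of the TPM means printed beside them. In WT between days 0 and 2, Plin1, which coats lipid droplets, rose 83.5-fold from 0.885 ± 0.391 to 158 ± 39.6 TPM (n = 3). Fabp4, a fatty acid carrier of adipocytes, rose 71.5-fold from 42 ± 36.6 to 2480 ± 500 TPM. Sema3g, Serpina3m and Adamts15 rose 65.5-fold, 60.3-fold and 58.7-fold. The adipogenic regulators Pparg and Cebpa rose 4.48-fold and 7.64-fold. Gjb2, a gap junction gene, was 46.9-fold lower at day 2 (1.92 ± 1.01 against 141 ± 61.8 TPM), and Mmp12, Serpinb2, Ankrd1 and Siglecg were 31.3-fold, 30.6-fold, 27.5-fold and 24.3-fold lower. Without WT replicate 2 of day 0, Fabp4 rose 113-fold, and Serpinb2, Mmp12, Ankrd1 and Siglecg were 13.1-fold, 19.9-fold, 18-fold and 14.8-fold lower, without WT replicate 1 Serpinb2 was 49.4-fold and without WT replicate 3 Ankrd1 was 41.4-fold lower. In KO the largest rises were those of Plin1 (72.9-fold), Serpina3m (67.4-fold), Fabp4 (64-fold), Adamts15 (49.5-fold) and Zbtb16 (49.2-fold). The largest falls in KO were those of Mmp12 (66.9-fold lower), Serpinb2 (46.3-fold), Gjb2 (41.7-fold), Aldh1a3 (29.6-fold) and Ankrd1 (28.3-fold). Serpinb2 was 20.6-fold lower without KO replicate 2 and 73.9-fold lower without KO replicate 1 of day 0.

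Gene groups were counted over the same first step. Among 17 adipocyte identity genes 15 rose and 0 fell in WT and in KO, and adjusted over the list alone 15 and 16 rose. Fatty acid oxidation genes rose in 16 of 19 cases in WT and KO (17 and 18 adjusted over the list alone). Of 30 cell cycle genes 21 rose in WT and 26 in KO, and adjusted over the list alone 29 rose in each. Cytosolic ribosomal protein genes rose in 38 of 38 cases in WT and in 32 of 38 in KO (38 and 36 adjusted over the list alone). Among 27 interferon response genes 21 fell in WT and 22 in KO (23 and 22 adjusted over the list alone). Myofibroblast genes fell in 15 of 20 cases in WT and 16 of 20 in KO (16 and 16 adjusted over the list alone). In WT 5267 genes were called, 3344 higher and 1923 lower at day 2, and in KO 5047, 3137 higher and 1910 lower. Both labels called 4537 genes in the same direction and 0 in opposite directions. The log2 changes of the labels correlated across genes at r = 0.98, although genes are not independent replicates. The split depends on scaling. The median change of all genes was 0.15 in WT without scaling and 0.014 after median-ratio scaling, which gave 2820 higher and 2532 lower genes in WT and 2704 higher and 2460 lower in KO. After that scaling the cell cycle median was still 1.67 and the ribosomal median 0.56 in WT. Without the day 0 pair numbered 2, whose libraries held little cell cycle RNA, the split in WT was 2995 higher and 2194 lower. The planned block by number called 6791 genes in WT and 6591 in KO.

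Between days 2 and 8 in WT, Cfd, which encodes the secreted protease adipsin, rose 192-fold from 0.903 ± 0.315 to 412 ± 248 TPM (n = 3). Adrb3, the adipocyte adrenergic receptor, rose 44.3-fold, Car3 34.2-fold, Mmp12 28.5-fold and the adipokine Retn 18.7-fold. Adipoq, which encodes adiponectin, rose 16.9-fold and Mlxipl, a glucose-responsive regulator of lipogenesis, 9.69-fold. Sema3g, Agtr2, Draxin, Adamts15 and Gdf10 were 56.2-fold, 42.9-fold, 18.2-fold, 15.9-fold and 15.4-fold lower. Without WT replicate 3 of day 8, Car3 rose 20.7-fold, Mmp12 16.3-fold and Gdf10 was 8.37-fold lower. Without WT replicate 2, Car3 rose 57.5-fold and Mmp12 59.1-fold, and without WT replicate 1 Gdf10 was 26.4-fold lower. In KO Cfd rose 218-fold, Adrb3 and Car3 20-fold each (Car3 31.3-fold without KO replicate 2 of day 8), Gjb2 18.4-fold and Hspb7 16.6-fold, and Sema3g, Gfra1, Agtr2, Adamts15 and Draxin were 45.9-fold, 25.1-fold, 24.4-fold, 20.9-fold and 19.2-fold lower (Sema3g 69.9-fold without KO replicate 2 of day 2). Of 30 cell cycle genes 29 fell in WT and 30 in KO, with 30 in each adjusted over the list alone. Of 38 ribosomal protein genes 37 fell in WT and 36 in KO, with 38 in each adjusted over the list alone. Interferon response genes rose in 24 of 27 cases in WT and in 14 of 27 in KO (25 and 18 adjusted over the list alone). Of 16 macrophage markers 8 rose in WT and 4 in KO (9 and 4 adjusted over the list alone). The 2 day 8 libraries numbered 3 stood apart there, with macrophage markers summing to 13440 TPM in WT and 8500 TPM in KO against 2336 to 3575 TPM in the other day 8 libraries. In all, 3807 genes were called in WT, 2025 higher and 1782 lower, and 3605 in KO, 2005 higher and 1600 lower (2287 without KO replicate 3 of day 2). The balance turned with scaling, to 2139 higher and 2161 lower in WT and 1925 and 2047 in KO after median-ratio scaling, and to 1951 and 2385 in WT and 1857 and 2136 in KO after quantile normalization. The labels shared 2982 calls in the same direction and 0 in opposite directions, and their changes correlated across genes at r = 0.94.

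**Figure D2:**
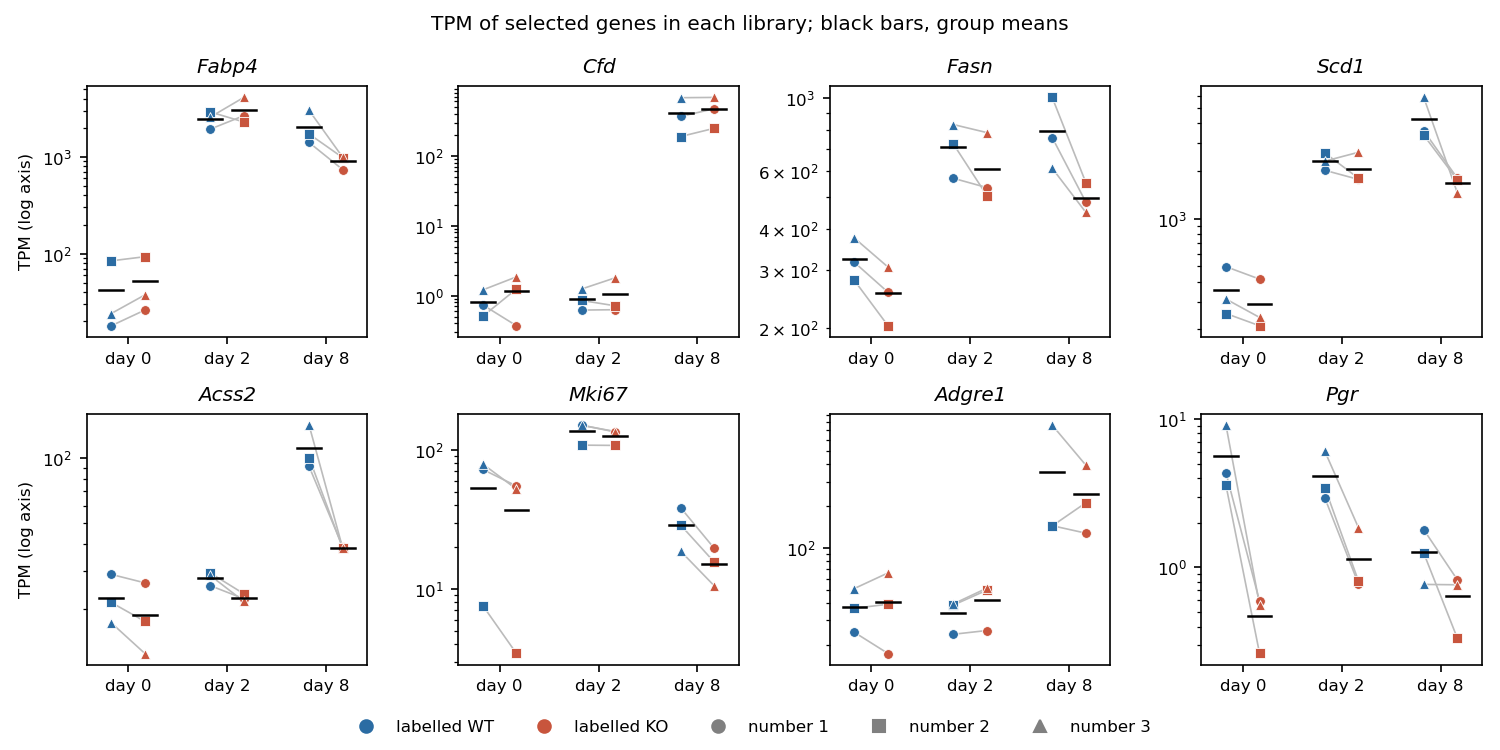
TPM on a log axis (y) in each library by day (x) for 8 genes, with libraries labelled WT in blue and KO in red, marker shape for the replicate number and black bars for group means of 3 libraries. Cfd rises from 0.903 to 412 TPM in WT between days 2 and 8, and Acss2 separates the labels at day 8 with 111 TPM in WT and 38.4 TPM in KO.

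At day 0, before differentiation, Pgr, the progesterone receptor, was 4.28-fold lower in KO than in WT (0.471 ± 0.181 against 5.65 ± 2.97 TPM, n = 3), and Dkk2, a secreted modulator of Wnt signalling, 4.2-fold lower (15.0 ± 2.76 against 66.3 ± 9.75 TPM). Igfbp5, which binds insulin-like growth factors, was 4.72-fold lower (7.75 ± 2.56 against 40.9 ± 13.9 TPM), Greb1, an oestrogen-responsive gene, 3.25-fold, and Hsd3b6, a steroid dehydrogenase, 2.93-fold. Crabp1, Tenm3, Edil3, Gas2 and Cgnl1 were 2.37-fold, 1.91-fold, 1.73-fold, 1.63-fold and 1.6-fold lower. Only 3 genes met the naming rule in the other direction. These were Pcolce2, an enhancer of procollagen processing (1.91-fold higher, 18.8 ± 7.2 against 9.36 ± 3.71 TPM), Bmp6 (1.64-fold) and Smurf2 (1.27-fold), apart from members of the lists. Pgr lies on chromosome 9 (8899833 to 8968611, plus strand), Dkk2 on chromosome 3 (132085292 to 132180304, plus), Igfbp5 on chromosome 1 (72857932 to 72874884, minus) and Pcolce2 on chromosome 9 (95637601 to 95698096, plus). The unblocked fit called Pgr (adjusted p = 0.0312) and Dkk2 (adjusted p = 0.026) and no other gene, with 98 genes at an unadjusted p below 0.05. With sample quality weights the unblocked fit called 432 genes, 264 higher and 168 lower. Dkk2 was no longer called without any 1 of the 6 day 0 libraries, KO replicate 2 of day 2, or WT replicate 2 or KO replicate 1 of day 8 (adjusted p 0.0501 to 0.167). Pgr was not called without any 1 day 0 library other than WT replicate 2, without WT replicate 2 or KO replicates 1 or 2 of day 2, or without WT replicate 2 or KO replicate 1 of day 8 (adjusted p 0.0519 to 0.264). The blocked fit called 62 genes, 31 higher and 31 lower, each moving the same way in all 3 pairs. The split was 30 higher and 40 lower after median-ratio scaling and 25 and 42 after quantile normalization. Without the day 0 pair numbered 2 it called 16 genes, 15 of them among the 62. Without the day 8 pair numbered 3 it called 765 and with quality weights 754, and the block within day 0 called 485, each with all 62 among them.

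Cholesterol synthesis genes were lower in KO at day 0 as a group. All 23 members lay below 0, with a median log2 difference of -0.31. In the blocked fit 1 of them, Dhcr7 (1.3-fold lower), fell over all genes and 11 fell adjusted over the list alone, while Lss (log2 difference -0.55, adjusted p = 0.0664) did not pass. The list was called with adjusted p = 8.06e-14, and with adjusted p = 0.258 with an estimated correlation. ATF4 targets, which serve amino acid synthesis and stress responses, had a median of -0.18 with 18 of 19 members below 0. Phgdh, the entry enzyme of serine synthesis, was 1.41-fold lower, and 4 members fell adjusted over the list alone (list adjusted p = 2.05e-07, and adjusted p = 0.258 with an estimated correlation). This list call was lost without WT replicate 2 (adjusted p = 0.173) or KO replicate 3 (adjusted p = 0.409) of day 0. Collagen and matrix genes had a median of -0.13 with 21 of 27 below 0. Col6a1 and Col6a2 were 1.42-fold and 1.53-fold lower, and 5 members fell adjusted over the list alone (list adjusted p = 5.63e-07, and adjusted p = 0.451 with an estimated correlation). De novo lipogenesis had a median of -0.15, with 0 of 17 members called over all genes by limma and 4 lower adjusted over the list alone (list adjusted p = 0.000404, and adjusted p = 0.451 with an estimated correlation). It was not called without WT replicate 1 (median -0.017, adjusted p = 0.261) or KO replicate 2 (median 0.031, adjusted p = 0.295) of day 0.

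Cell cycle genes had a median of -0.25 at day 0, with 28 of 30 members below 0. Mki67, a proliferation marker, was 1.56-fold lower (36.8 ± 29 against 53 ± 39.5 TPM) in the blocked fit. Its unpaired log2 difference of -0.64 was 0.56 without KO replicate 2, -1.70 without WT replicate 2, -1.27 without KO replicate 1 and -1.23 without KO replicate 3 of day 0. In the list 10 members fell and 1 rose adjusted over the list alone. The list was called with adjusted p = 0.00166, and with adjusted p = 0.92 with an estimated correlation. The day 0 libraries numbered 2 stood apart in this group, with cell cycle genes summing to 328.8 TPM in WT and 332.6 TPM in KO against 798.9 to 1012 TPM in the other 4. Their inflammatory genes summed to 14770 and 14610 TPM against 7279 to 10190 TPM. The cell cycle medians of pairs 1, 2 and 3 were -0.16, -0.22 and -0.30. Leaving out 1 library of a pair sets its partner against the other libraries. Without WT replicate 1, WT replicate 3 or KO replicate 2 of day 0 the unpaired cell cycle median was 0.077 (adjusted p = 0.958), 0.085 (adjusted p = 0.647) or 0.49 (adjusted p = 0.0228). Adipocyte identity genes had a median of 0.19 with 14 of 17 above 0 and 0 called in limma over all genes or adjusted over the list alone. The list was called higher with adjusted p = 0.0105, and with adjusted p = 0.905 with an estimated correlation, and the call was lost in the blocked fit (adjusted p = 0.0633). Without WT replicate 1, WT replicate 3 or KO replicate 2 of day 0 adjusted p was 0.361, 0.269 or 0.839. Among the 12 adipocyte genes followed throughout, none passed at day 0. Pparg, Cebpa, Fabp4 and Fasn had log2 differences of 0.14, 0.49, 0.42 and -0.35. Markers of Schwann cells (median -0.39, 5 of 7 below 0, adjusted p = 0.000375) and endothelial cells (median -0.37, 5 of 8 below 0, adjusted p = 0.0136) were called lower, each with adjusted p = 0.258 with an estimated correlation. Adjusted over the list alone 4 Schwann and 1 endothelial markers fell. Neither marker list was called without WT replicate 2 (adjusted p 0.273 and 0.921) or KO replicate 1 (adjusted p 0.153 and 0.562) of day 0. In all, 10 lists were called at day 0 and 0 with an estimated correlation, and 16 without WT replicate 2 or 20 without KO replicate 1 of day 0.

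At day 2, after the inducing mixture, several complement genes were higher in KO. Serping1, the C1 inhibitor, rose 1.65-fold (620 ± 301 against 381 ± 204 TPM, n = 3) and the complement component C4b 1.54-fold (239 ± 40.2 against 156 ± 37 TPM). The complement proteases C1s1 and C1ra rose 1.4-fold and 1.38-fold. Ltbp2, a microfibril protein, rose 1.62-fold (1020 ± 216 against 633 ± 153 TPM), Pcsk6, a proprotein convertase, 1.67-fold, and Epas1, which encodes the hypoxia-inducible factor HIF-2alpha, 1.69-fold (243 ± 30.2 against 145 ± 32.8 TPM). Tmem140, Abcd2, Vsir, Aldh1a3, Dchs1 and Trpv2 rose between 1.48-fold and 1.64-fold, and the chemokine genes Ccl8 and Ccl11 1.73-fold and 1.84-fold. Ngfr, the low-affinity neurotrophin receptor, was 3.14-fold lower (6.89 ± 4.29 against 22.8 ± 8.65 TPM), Igfbp5 2.56-fold, Nrn1 2.04-fold and the basement membrane gene Nid2 1.75-fold (223 ± 38.2 against 394 ± 76.9 TPM). Cdkn2a, Epha7, Phgdh, Plau, Rin1, Sdc4 and Nxn were between 1.32-fold and 1.54-fold lower. Epas1 lies on chromosome 17 (86753700 to 86833410, plus strand), Serping1 on chromosome 2 (84765387 to 84775444, minus) and C4b on chromosome 17 (34728380 to 34743882, minus). These calls came from the blocked fit, which called 90 genes, 58 higher and 32 lower, each in the same direction in all 3 pairs (49 and 36 after median-ratio scaling). Without the day 0 pair numbered 2 it kept 33 of the 90. Without the day 8 pair numbered 3 it called 1277 genes and with quality weights 1868, and the block within day 2 called 599, each with all 90 among them. The unblocked limma fit called 0 genes, with 128 at an unadjusted p below 0.05.

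Interferon response genes were all above 0 at day 2, 27 of 27, with a median log2 difference of 0.52. Bst2, which tethers budding virus, rose 1.43-fold (40 ± 6.06 against 27.9 ± 5.71 TPM), and 15 members rose adjusted over the list alone. Oasl2, Gbp3 and Ifih1 had log2 differences of 1.26, 1.13 and 0.73 without passing over all genes. The list was called with adjusted p = 2.43e-22, and with adjusted p = 0.468 with an estimated correlation. Of 13 complement genes 11 lay above 0 with a median of 0.48. Over all genes 5 rose, and adjusted over the list alone 9 rose and 1 fell (list adjusted p = 0.000846, and adjusted p = 0.537 with an estimated correlation). The complement list was not called without KO replicate 2 of day 2 (adjusted p = 0.257). Its medians in pairs 1, 2 and 3 were 0.43, 0.44 and 0.52. Macrophage markers had medians of -0.13, 0.35 and 0.21 in these pairs, with 13, 0 and 0 of 16 below 0. Fry in the blocked fit also called complement (adjusted p = 0.0143) and matrix proteases and inhibitors (adjusted p = 0.0143), the only 2 lists it called at day 2. Adamts5, which cleaves the proteoglycan aggrecan, rose 1.36-fold in the latter list, whose median was 0.13 with 14 of 17 above 0. Its camera test gave adjusted p = 0.00883, and adjusted p = 0.468 with an estimated correlation, and 2 members rose adjusted over the list alone. It was not called by camera without WT replicate 3 (adjusted p = 0.269) or KO replicate 2 (adjusted p = 0.174) of day 2. Of 20 FOXO targets 13 lay above 0 with a median of 0.14, and 5 rose adjusted over the list alone against 0 over all genes in limma (list adjusted p = 0.0177, and adjusted p = 0.52 with an estimated correlation). The FOXO list was not called without WT replicate 3 (adjusted p = 0.0681), KO replicate 1 (adjusted p = 0.0832) or KO replicate 3 (adjusted p = 0.0628) of day 2.

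Groups of metabolic and growth genes lay below 0 at day 2. Cholesterol synthesis had a median of -0.18 with 21 of 23 below 0 and 4 lower adjusted over the list alone (list adjusted p = 3.59e-05). Glycolysis genes had a median of -0.18 with 14 of 18 below 0 and none called adjusted over the list alone (list adjusted p = 2.09e-06). ATF4 targets had a median of -0.20 with 15 of 19 below 0 and 2 lower adjusted over the list alone, among them Phgdh, 1.5-fold lower (list adjusted p = 0.00078). All 3 lists gave adjusted p = 0.52 with an estimated correlation. Ribosomal protein genes lay below 0 in 38 of 38 cases with a median of -0.13 (list adjusted p = 2.52e-07, and adjusted p = 0.834 with an estimated correlation). The ribosomal medians were below 0 in each pair (-0.082, -0.22 and -0.11). Without KO replicate 2 of day 2, which leaves its WT partner unpaired, the median was 0.007 (adjusted p = 0.767). Adipocyte identity genes were not called at day 2 (median 0.072, adjusted p = 0.0761). Their medians in pairs 1, 2 and 3 were 0.44, -0.35 and 0.42, with 1, 15 and 0 of 17 members below 0. Fatty acid uptake and triglyceride synthesis (0.18, -0.59 and 0.115) and lipolysis genes (0.19, -0.44 and 0.19) split the same way. None of the 12 adipocyte genes passed, with log2 differences of -0.09 for Pparg, 0.14 for Cebpa, 0.26 for Fabp4 and -0.23 for Fasn. In all, 13 lists were called at day 2 and 0 with an estimated correlation.

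At day 8, when the cultures expressed adipocyte genes in both labels, genes of fatty acid synthesis and storage were lower in KO. Acss2, which makes cytosolic acetyl-CoA from acetate, was 2.79-fold lower (38.4 ± 0.342 against 111 ± 26.9 TPM, n = 3), and Scd1, the main stearoyl-CoA desaturase, 2.48-fold (1670 ± 189 against 4270 ± 1370 TPM). Fasn, the fatty acid synthase, was 1.57-fold lower (496 ± 53.2 against 792 ± 199 TPM), Acly 1.41-fold and Me1, the cytosolic malic enzyme, 1.67-fold. Fabp4 was 2.17-fold lower (906 ± 144 against 2060 ± 860 TPM) and Lpl, the lipoprotein lipase, 1.53-fold. Adjusted p in the blocked fit was 0.000824 for Acss2, 0.00988 for Scd1, 0.0107 for Fasn and 0.0203 for Fabp4. The 10 lower genes named by size were Nabp1 (4.04-fold lower, 64.9 ± 29.8 against 242 ± 11.5 TPM), Il1rn (3.94-fold), Aldh1a2 (3.22-fold), Orm1 (3.17-fold), Aldh1a7 (2.98-fold), Acaa1b (2.81-fold), Acss2, Angptl4 (2.63-fold), Scd1 and Tenm4 (2.47-fold). Il1rn stood at 282.5 TPM in WT replicate 3 of day 8, without which it was 1.78-fold lower, and 6.54-fold lower without WT replicate 2. Acss2 lies on chromosome 2 (155517948 to 155585724, plus strand), Scd1 on chromosome 19 (44394455 to 44407879, minus), Fasn on chromosome 11 (120805846 to 120824547, minus) and Fabp4 on chromosome 3 (10204088 to 10208576, minus).

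Among the genes named by size in KO at day 8, Gdf6, a BMP family ligand, rose 3.81-fold (64 ± 30.6 against 19.9 ± 16 TPM, n = 3), and Gabra3, a GABA receptor subunit, 3.52-fold (15.3 ± 1.25 against 4.02 ± 2.21 TPM). Smpd3, Gria4, Fbln7, Piezo2, Kif1a and Sytl5 rose 2.82-fold, 2.7-fold, 2.61-fold, 2.58-fold, 2.35-fold and 2.2-fold. Inhbb, an activin subunit, rose 2.12-fold (155 ± 42.9 against 73.7 ± 23.8 TPM). Some sizes leaned on the macrophage-rich WT library numbered 3, without which Gdf6 was 2.24-fold, Piezo2 1.64-fold and Kif1a 1.52-fold higher. Without WT replicate 2 Gdf6 was 5.83-fold higher, and without the day 8 pair numbered 3 Smpd3 was 1.71-fold higher. Gdf6 lies on chromosome 4 from 9844372 to 9862345 on the plus strand. The blocked fit called 720 genes, 442 higher and 278 lower, each in the same direction in all 3 pairs. After median-ratio scaling the split was 336 higher and 367 lower, and after quantile normalization 415 and 357. The unblocked limma fit called 0 genes, with 500 at an unadjusted p below 0.05 and a smallest adjusted p of 0.13. A block fitted to day 8 alone also called 0 in limma (smallest adjusted p 0.307, 1488 genes at an unadjusted p below 0.05). The same block within days 0 and 2, with as many libraries, called 485 and 599, so fewer libraries alone do not explain the 0. Without the day 8 pair numbered 3 the blocked fit called 680 genes and kept 434 of the 720. At days 0 and 2 it then called 765 and 1277, against 62 and 90. The day 8 calls rest on the spread pooled over 3 days, which is thus likely too small for them, as are their adjusted p-values. At day 8 the blocked fit called 324 without the day 0 pair numbered 2 and 1528 with quality weights.

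**Figure D3:**
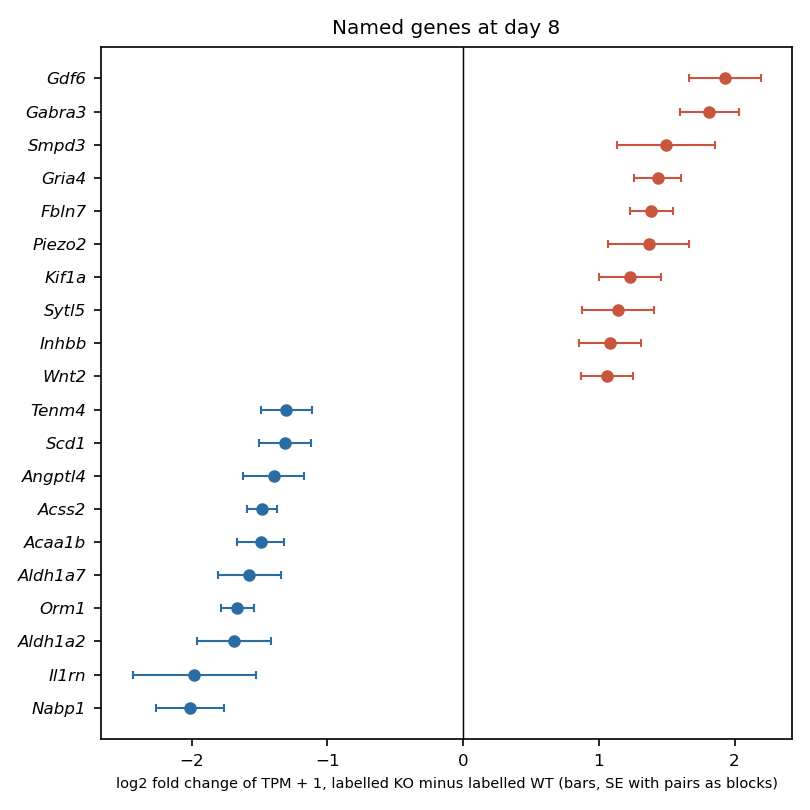
Log2 fold change of KO against WT at day 8 (x axis) for 20 named genes (y axis), with bars for ± 1 SE. Points and bars come from the blocked fit to all 18 libraries. The bars use the spread pooled over the 3 days, not that of the 3 day 8 pairs alone. Values run from -2.01 for Nabp1 to 1.93 for Gdf6.

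Camera called 7 lipid and oxidative lists lower at day 8, of which fry in the blocked fit called de novo lipogenesis and fatty acid oxidation only. Of 17 de novo lipogenesis genes 9 fell and 0 rose in the blocked fit over all genes, and 9 fell adjusted over the list alone, with a median log2 difference of -0.44 (list adjusted p = 6.02e-12, adjusted p = 0.146 with an estimated correlation, and fry adjusted p = 0.00707). Of 16 genes of fatty acid uptake and triglyceride synthesis 4 fell, among them Agpat2 (2.27-fold lower, 54.6 ± 10.6 against 124 ± 16.6 TPM), Lpl and Fabp5 (1.8-fold), and 10 fell adjusted over the list alone. The median was -0.63 (list adjusted p = 9.56e-10, adjusted p = 0.221 with an estimated correlation, and fry adjusted p = 0.0626). Adipocyte identity genes fell in 5 of 17 cases and in 7 adjusted over the list alone, among them Fabp4, Cidec (2.36-fold lower), Adrb3 (1.7-fold) and Adipor2 (1.35-fold), with a median of -0.38 (list adjusted p = 1.86e-09, adjusted p = 0.225 with an estimated correlation, and fry adjusted p = 0.103). Lipolysis and lipid droplet genes fell in 4 of 12 cases and in 9 adjusted over the list alone, including Plin2 (2.13-fold lower) and the lipase inhibitor G0s2 (1.89-fold). Plin2 was 1.14-fold lower without WT replicate 3 of day 8, and Cidec 3.54-fold lower without WT replicate 1. Their median was -0.53 (list adjusted p = 3.31e-06, adjusted p = 0.225 with an estimated correlation, and fry adjusted p = 0.0947). Fatty acid oxidation genes lay below 0 in 19 of 19 cases. Over all genes 7 fell, such as Acadm (1.47-fold lower) and Acox1 (1.37-fold), and 18 fell adjusted over the list alone (median -0.29, list adjusted p = 1.61e-12, adjusted p = 0.225 with an estimated correlation, and fry adjusted p = 0.0246). Respiratory chain and TCA cycle genes lay below 0 in 27 of 27 cases, with 9 lower over all genes, including Cyc1 (1.3-fold) and Aco2 (1.29-fold), and 22 adjusted over the list alone (median -0.25, list adjusted p = 2.9e-14, adjusted p = 0.27 with an estimated correlation, and fry adjusted p = 0.0521). The 13 protein-coding genes of the mitochondrial genome took 2.01%, 2% and 2.8% of TPM in WT and 1.82%, 1.83% and 2.1% in KO, lower in 3 of 3 pairs. Glycolysis genes had a median of -0.36 with 0 of 18 called over all genes in limma and 10 lower adjusted over the list alone (list adjusted p = 1.08e-11, adjusted p = 0.221 with an estimated correlation, and fry adjusted p = 0.108). The glycolysis medians of pairs 1, 2 and 3 were -0.20, -0.10 and -0.80. The 7 camera calls held without any 1 library.

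Several regulators and markers of adipocytes did not pass. The regulators Pparg, Cebpa, Srebf1 and Mlxipl had log2 differences of -0.15, -0.36, -0.13 and -0.29 at day 8 in the blocked fit (adjusted p 0.396, 0.175, 0.29 and 0.182). Adipoq (-0.39, adjusted p = 0.246), Plin1 (-0.35, adjusted p = 0.418), Slc2a4 (-0.74, adjusted p = 0.0709) and Cd36 (-1.21, adjusted p = 0.0568) also missed the threshold. Acly, Fasn, Fabp4 and Lpl were the 4 of the 12 followed genes that fell. Branched-chain amino acid breakdown genes had a median of -0.20 with 15 of 16 below 0. Pcca and Pccb, the propionyl-CoA carboxylase subunits, were each 1.26-fold lower, and 5 fell adjusted over the list alone (list adjusted p = 0.00013, and adjusted p = 0.393 with an estimated correlation). Without WT replicate 3 of day 8 this list was not called (adjusted p = 0.162). Cholesterol synthesis was not called at day 8 (median -0.087, adjusted p = 0.067), although Dhcr7 (1.57-fold lower), Insig1 (1.66-fold) and Cyp51 (1.23-fold) fell. Its medians in pairs 1, 2 and 3 were -0.19, -0.26 and 0.32. It was called lower without WT replicate 3 of day 8 (median -0.23, adjusted p = 3.49e-10), KO replicate 1 of day 8 (-0.13, adjusted p = 0.000248), or WT replicate 2 (adjusted p = 0.0425) or KO replicate 2 (adjusted p = 0.0334) of day 0.

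**Figure D4:**
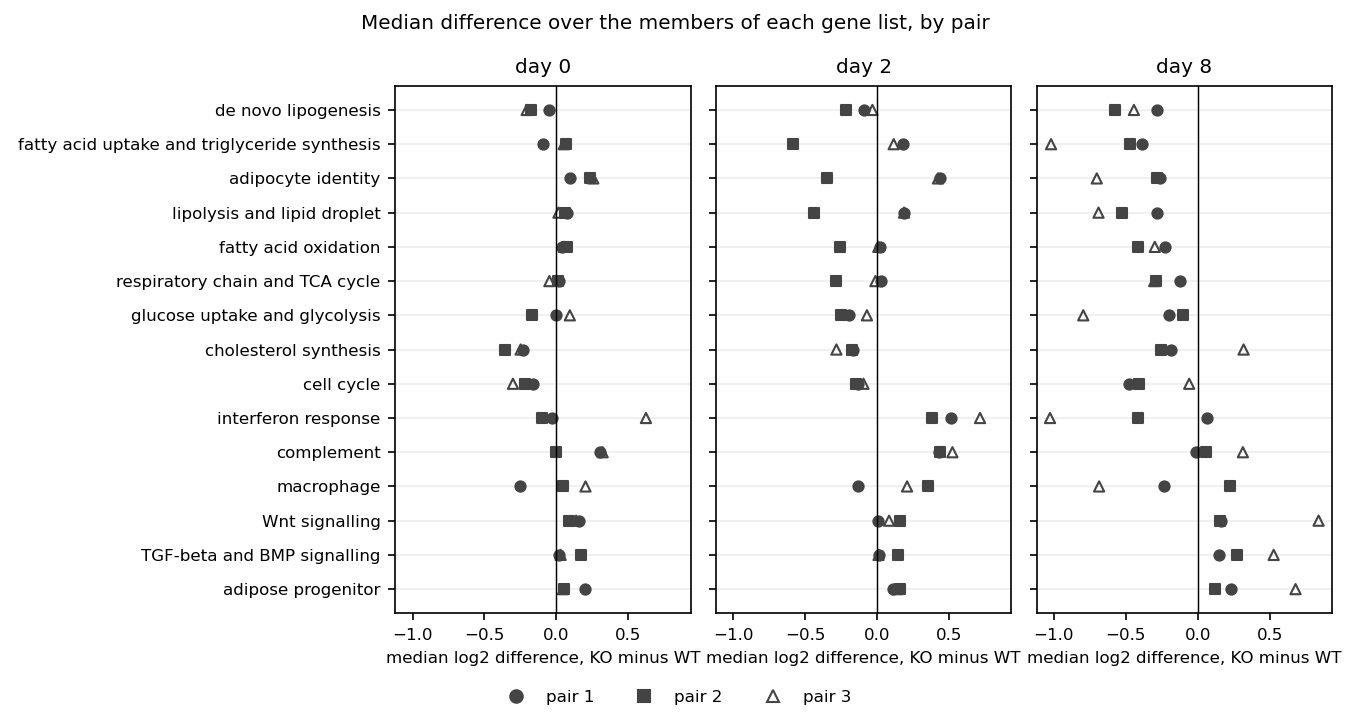
Median log2 difference of KO minus WT (x axis) over the members of 15 gene lists (y axis), with a point for each of the 3 pairs of libraries and a panel for each day. At day 8 the adipocyte identity medians of pairs 1 to 3 were -0.26, -0.28 and -0.70, and the Wnt signalling medians 0.16, 0.15 and 0.84.

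Camera called developmental signalling and progenitor lists higher at day 8, although most of their members did not pass. Of 21 Wnt signalling genes 19 lay above 0 (median 0.38). Wnt2 rose 2.09-fold (34.1 ± 4.85 against 16.8 ± 6.81 TPM, n = 3), Axin2, a feedback target of the pathway, 2.06-fold and Dkk3 1.95-fold, and 5 rose over all genes and 8 rose and 1 fell adjusted over the list alone (list adjusted p = 1.07e-05, adjusted p = 0.348 with an estimated correlation, and fry adjusted p = 0.0352). TGF-beta and BMP signalling genes lay above 0 in 17 of 21 cases, with 5 higher over all genes, among them Smad3 (1.44-fold), the BMP antagonist Grem1 (1.71-fold) and Id1 (1.3-fold), and 11 adjusted over the list alone (median 0.33, list adjusted p = 0.00164, adjusted p = 0.27 with an estimated correlation, and fry adjusted p = 0.0246). Of 18 progenitor genes 6 rose and 1 fell, and 10 rose and 2 fell adjusted over the list alone. Dpp4, which marks early interstitial progenitors, rose 2.25-fold and Pdgfra 1.26-fold (468 ± 49.4 against 371 ± 1.74 TPM), while Cd55 fell by 0.62 on the log2 scale (list adjusted p = 0.00211, and adjusted p = 0.225 with an estimated correlation). Without KO replicate 3 of day 8 the change of Cd55 was -1.29, and without WT replicate 3 it was 0.058. p53 targets rose in 4 of 20 cases, including Ccng1 (1.4-fold) and Eda2r (1.37-fold), and 12 rose and 1 fell adjusted over the list alone (median 0.26, list adjusted p = 0.0182, adjusted p = 0.225 with an estimated correlation, and fry adjusted p = 0.0358). HOX genes rose in 2 of 24 cases by either adjustment, such as Hoxc9 (1.53-fold), with a median of 0.27 (list adjusted p = 0.00213, and adjusted p = 0.628 with an estimated correlation). The medians were above 0 in each pair for Wnt (0.16, 0.15 and 0.84), TGF-beta and BMP (0.14, 0.27 and 0.53), progenitor (0.23, 0.12 and 0.68), p53 (0.18, 0.082 and 0.48) and HOX genes (0.089, 0.10 and 0.55). Without the macrophage-rich WT library numbered 3, which leaves its KO partner unpaired, the medians were 0.032 for Wnt (adjusted p = 0.886), 0.097 for TGF-beta and BMP (adjusted p = 0.805), 0.17 for progenitor (adjusted p = 0.693) and 0.076 for HOX genes (adjusted p = 0.886), while the p53 list had adjusted p = 0.0502. The p53 list was also not called without WT replicate 2 (adjusted p = 0.124), KO replicate 1 (adjusted p = 0.0812) or KO replicate 3 (adjusted p = 0.0805), nor the HOX list without KO replicate 2 (adjusted p = 0.101).

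Some immune and proliferation genes were lower in KO at day 8, and the pairs differed in the immune and cell cycle groups. Cxcl12, a stromal chemokine gene, was 2.46-fold lower (348 ± 96.8 against 858 ± 224 TPM, n = 3) and Il6 2.32-fold. Inflammatory genes had a median of -0.36 with 15 of 20 below 0, 2 lower and 1 higher over all genes, and 4 lower and 1 higher adjusted over the list alone (list adjusted p = 0.00414, and adjusted p = 0.575 with an estimated correlation). Interferon response genes lay below 0 in 26 of 27 cases with a median of -0.52. Ifi44 was 2.14-fold lower and 3 fell adjusted over the list alone (list adjusted p = 5.76e-12, and adjusted p = 0.27 with an estimated correlation). The pair numbered 3 differed most in both groups, with interferon medians of 0.065, -0.41 and -1.03 and inflammatory medians of 0.022, -0.048 and -0.95 in pairs 1, 2 and 3. Macrophage markers lay below 0 in 16 of 16 cases (median -0.23, list adjusted p = 0.0182, and adjusted p = 0.698 with an estimated correlation), with Fcgr1 (1.75-fold lower) the 1 member called by either adjustment. The macrophage medians of pairs 1, 2 and 3 were -0.23, 0.22 and -0.69. Without WT replicate 3 of day 8 the macrophage list was called higher (median 0.53, adjusted p = 0.0234) and the inflammatory median was 0.029 (adjusted p = 0.239). Without KO replicate 1 the macrophage list had adjusted p = 0.909, and without KO replicate 3 the inflammatory list had adjusted p = 0.0932. Cell cycle genes fell in 10 of 30 cases, and 17 fell and 1 rose adjusted over the list alone, with Mki67 1.8-fold lower (15.2 ± 4.53 against 28.6 ± 9.86 TPM), Top2a 1.46-fold and Cenpa 1.45-fold. The list had adjusted p = 0.00305, adjusted p = 0.698 with an estimated correlation and fry adjusted p = 0.0358. It was not called without WT replicate 1 (adjusted p = 0.413), WT replicate 2 (adjusted p = 0.155) or KO replicate 3 (adjusted p = 0.399) of day 8. The cell cycle medians of pairs 1, 2 and 3 were -0.48, -0.41 and -0.06, with 29, 28 and 16 of 30 members below 0. In all, 20 lists were called at day 8 and 0 with an estimated correlation, while fry in the blocked fit called 7.

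Some differences between labels were present on every day. The blocked fit called 13 genes higher in KO at all 3 days, namely Adamts5, Aldh1a3, Cfh, Epas1, Gstm1, Hsd11b1, Maff, Mafk, Pcolce2, Pcsk6, Pltp, Rgl1 and Wnt11, and 6 lower, namely Cpxm2, Hsd3b6, Nrn1, Phgdh, Pi15 and Plau. Adamts5 was 1.6-fold, 1.36-fold and 1.56-fold higher at days 0, 2 and 8, with 340 ± 98.1 against 213 ± 67.7 TPM at day 0 (n = 3). Gstm1, a glutathione transferase, had log2 differences of 0.57, 0.41 and 0.51. Several of these genes lie outside the naming rule and were named after their values were seen. Days 0 and 2 shared 16 higher and 8 lower genes against 0.14 and 0.08 for independent lists, days 2 and 8 shared 22 and 11 against 1.96 and 0.68, and 0 genes were called in opposite directions. The days had no libraries in common, but the blocked fit estimates each gene's spread once for all days, which adds to such overlaps. Same-numbered libraries of different days also deviated together, with correlations above 0.1 in 33 of 36 pairs. The days may thus not be independent, and the overlaps are not a replication across independent days.

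Whether the label effect changed with time was tested by interactions. No gene was called in the unblocked limma fit for day 2 against day 0, day 8 against day 2 or day 8 against day 0, with 14, 98 and 96 genes at an unadjusted p below 0.05. The blocked fit called 0, 1 and 2 genes in limma, with 627, 1583 and 1468 at an unadjusted p below 0.05. Without the day 8 pair numbered 3 it called 22, 62 and 12, and with quality weights 28, 386 and 56. Without the day 0 pair numbered 2 it called 0, 0 and 0 in limma (smallest adjusted p 0.999, 0.111 and 0.151, with 403, 1413 and 1010 genes at an unadjusted p below 0.05), so the calls named next were lost. Orm1, which encodes the acute-phase protein orosomucoid, rose to 9.78 ± 6.58 TPM in WT but to 2.17 ± 1.18 TPM in KO at day 8, a log2 difference of differences of -1.70 against day 0 (SE 0.17, adjusted p = 0.0295) and -1.64 against day 2 (adjusted p = 0.0411). Slc16a12, a membrane transporter gene, had a difference of differences of 1.33 between days 8 and 0 (SE 0.15, adjusted p = 0.0352). For day 8 against day 0 camera called 22 lists, 9 higher and 13 lower, with adjusted p between 0.21 and 0.686 with an estimated correlation. The largest medians were those of interferon response (-0.72), adipocyte identity (-0.68), fatty acid uptake and triglyceride synthesis (-0.60) and inflammatory genes (-0.56). The inflammatory list was not called without WT replicate 1 (adjusted p = 0.387) or KO replicate 2 (adjusted p = 0.894) of day 0. Fry in the blocked fit called 0 lists.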

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

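The tests of explanations below were chosen after the result was seen, except that of the oestrogen receptor targets, and the counts over other splits of the samples were run for every comparison. All groups held 3 libraries, so single libraries were not tested against the rest of their group. The results listed here met a rule on differences between groups, namely that the effect of the KO label differed between days in a test of the difference itself.

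For day 8 against day 0, 22 gene lists had a log2 difference of differences that camera called. Below 0 were the medians of interferon response (-0.72), adipocyte identity (-0.68), fatty acid uptake and triglyceride synthesis (-0.60), inflammatory (-0.56), lipolysis and lipid droplet (-0.53), glycolysis (-0.33), fatty acid oxidation (-0.30), de novo lipogenesis (-0.30), respiratory chain and TCA cycle (-0.23) and branched-chain amino acid breakdown genes (-0.19). The medians of pentose phosphate (-0.16), brown and beige adipocyte (-0.16) and NRF2 target genes (-0.15) were also below 0. Above 0 were Wnt signalling (0.27), adipose progenitor (0.26), cholesterol synthesis (0.23), TGF-beta and BMP signalling (0.22), positional HOX (0.21), collagen and matrix (0.20), p53 target (0.19), unfolded protein response (0.15) and insulin signalling genes (0.13). None of the 22 was called with an estimated correlation. Of 100 splits drawn from 200, 3 gave as many lists as the real 22 (highest other 25). Of the 32 splits that parted all 6 pairs as the real one did, 4 gave as many (highest other 24), so chance was not excluded. Among genes, Orm1 differed between days 8 and 0 (-1.70) and between days 8 and 2 (-1.64), and Slc16a12 between days 8 and 0 (1.33), in the blocked fit only. Without the day 0 pair numbered 2 that fit called 0 genes in limma for either interaction (smallest adjusted p 0.111 and 0.151, with 1413 and 1010 genes at an unadjusted p below 0.05), and with quantile normalization Orm1 was not called for day 8 against day 2 (adjusted p = 0.0568). The unblocked limma fit called 0 genes for the 3 interactions, so all 100 splits drawn for each gave at least as many (highest others 1, 2 and 1436), and at an unadjusted p below 0.05 there were 14, 98 and 96 genes.

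Of these interaction lists, interferon response, adipocyte identity, fatty acid uptake, lipolysis, glycolysis, fatty acid oxidation, de novo lipogenesis and respiratory chain genes stayed called without any 1 library. Without WT replicate 3 of day 8 the medians were 0.013 for Wnt (adjusted p = 0.979), 0.14 for progenitor (0.91), 0.007 for cholesterol synthesis (0.409), 0.015 for TGF-beta and BMP (0.924), -0.044 for HOX (0.528), 0.076 for NRF2 (0.784) and 0.11 for insulin signalling genes (0.0945). For branched-chain amino acid (-0.017, adjusted p = 0.105), pentose phosphate (-0.034, 0.453) and brown and beige genes (-0.078, 0.0582) the call was lost as well, and collagens were called lower (-0.076, 0.00742). Further calls were lost without other libraries. At day 0, the progenitor list was lost without WT 2 (adjusted p = 0.134) and the inflammatory list without WT 1 (0.387) or KO 2 (0.894). The NRF2 list was lost without WT 1, WT 3 or KO 2 of day 0 (0.12 to 0.644), and insulin signalling without KO 1 of day 8 (0.0523). Cholesterol synthesis was lost without WT 2 or KO 2 of day 0 or KO 1 of day 8 (0.0557 to 0.335), and collagens without WT 2 or KO 1 of day 0 or KO 1 or 2 of day 8 (0.201 to 0.425). The HOX list was lost without WT 1, WT 3 or KO 2 of day 0 or KO 2 of day 8 (0.125 to 0.621), and TGF-beta and BMP without WT 2, KO 1 or KO 3 of day 0 or KO 1 or 2 of day 8 (0.07 to 0.831). The p53 list was lost without WT 2, KO 1 or KO 3 of day 0 or WT 2 or KO 1 of day 8 (0.0551 to 0.201). Pentose phosphate genes were lost without WT 2, WT 3 or KO 1 of day 0 or WT 2 or KO 2 of day 8 (0.0605 to 0.362). Brown and beige genes were lost without WT 1, WT 3 or KO 2 of day 0 or WT 2, KO 1 or KO 3 of day 8 (0.0758 to 0.698). The unfolded protein response was lost without WT 1, KO 2 or KO 3 of day 0 or WT 1, WT 2 or KO 3 of day 8 (0.0665 to 0.66).

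Other splits of the 6 libraries of a comparison number only 10, too few for a share under 0.05. At day 0, 2 of the 10 gave as many genes as the real 2 (highest other 2240), and 7 gave as many lists as the real 10 (highest other 19). The split with 2240 genes put both day 0 libraries numbered 2 on the same side, which shows a structure of the samples other than their labels. At day 2, 10 of the 10 splits gave at least the real 0 genes called by limma (highest other 1, 128 at an unadjusted p below 0.05), and 5 gave as many lists as the real 13 (highest other 20). At day 8, 10 of the 10 gave at least the real 0 genes called by limma (highest other 2, 500 at an unadjusted p below 0.05), and 3 gave as many lists as the real 20 (highest other 21). In each of the 4 day comparisons only the real split, 1 of 10, gave as many genes (5267 and 3807 in WT, 5047 and 3605 in KO, highest other 0). In the blocked fit the 4 splits of a day that part all 3 pairs were also too few. Only the real one, 1 of 4, gave the 62, 90 and 720 genes of days 0, 2 and 8 (highest other 0 each). Over the 3 days together, 1 of 64 splits that part all 9 pairs gave as many genes as the real 872 (highest other 223) and 1 of 64 as many lists as the real 46 (highest other 45). A share of 1 in 64 is the smallest this test can give, and the list sum only narrowly exceeded the highest other. The splits also treat the days as separate, whereas same-numbered libraries of different days correlated above 0.1 in 33 of 36 pairs. If a number is a culture followed over the days, labels could not be reassigned day by day. Chance was therefore not excluded for either sum. The splits concern the pairing of labels with libraries and not the difference between 4-OHT and ethanol.

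Rictor was higher in the libraries labelled KO on every day. A difference in scaling was argued against, since the smallest of the 3 log2 differences after median-ratio scaling or quantile normalization was 0.31. An exchange of labels within a single pair was argued against, since 9 of 9 pairs had more Rictor in the library labelled KO. An exchange of the labels in every pair cannot be told apart from a deletion that leaves the rest of the transcript in place, since no internal coding exon exceeds 5.94% of the exonic sequence and exon-level reads were not in the table. A biological rise of Rictor mRNA after loss of the protein also stays open and was not tested.

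The lipid and oxidative lists were lower in KO at day 8, and so were the shares of TPM from the 13 protein-coding genes (2.01%, 2% and 2.8% in WT, 1.82%, 1.83% and 2.1% in KO) and the 2 ribosomal RNA genes (0.25%, 0.388% and 0.396%, against 0.164%, 0.198% and 0.161%) of the mitochondrial genome. The macrophage-rich pair numbered 3 as the whole source was argued against for 5 lists. These were de novo lipogenesis, fatty acid uptake and triglyceride synthesis, adipocyte identity, fatty acid oxidation and respiratory chain genes. The highest of their medians in pairs 1 and 2 was still -0.13. Lipolysis and glycolysis were not among the 5 (glycolysis medians by pair -0.20, -0.10 and -0.80). Scaling was argued against for the same 5 lists, since the highest median after either scaling was -0.26. Fewer or less mature adipocytes in KO may account for the pattern as well as a lower expression per adipocyte. The median of de novo lipogenesis minus that of adipocyte identity was -0.024, -0.29 and 0.26 in pairs 1, 2 and 3, with no common direction, and no cell counts were given, so this stays open beside an effect of Rictor loss on lipogenic expression.

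Pgr, Greb1 and Igfbp5, genes that respond to oestrogen in other tissues, were lower in KO at day 0. The day 0 pair numbered 2 as the source was argued against, since the highest of the 6 differences for the 3 genes in pairs 1 and 3 was -1.58. 4-OHT is also a ligand of the oestrogen receptor and was given only to KO, so it may have lowered them without any role of Rictor. Among 16 other measured targets of the receptor the median log2 difference was 0.011, with 8 below 0 and a fry p of 0.155 (limma), and members that go both ways decide nothing. The drug, the recombinase and the loss of Rictor remain inseparable in this design.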

How the results depend on the processing

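The alternatives set beforehand were the scalings, pseudocounts, filters, weights, the blocks by number or within a day, the estimated correlation and leaving out each library. All fits with a block by day and number were chosen after seeing the data. Where a call or count changed, the cause was not tested, except that fewer libraries or fewer genes were used where these are named. TPM keeps no read depth, so what depth limits among low genes is unknown. In the simulated data, built with paired libraries and the same spread on every day, the unblocked fit recovered 10.5% of 1.5-fold changes. The fit with a block by day and number recovered 75%, at the same number of libraries. Counts are genes called in limma unless lists are named. Of 884 values of named genes in the unblocked fit, 882 kept their call status, called or not, under median-ratio scaling and 882 under quantile normalization. It was kept by 883 values with a pseudocount of 0.1 and by 880 with a pseudocount of 5. Without an intensity trend 884 kept it, and without a filter on low values 880. The direction of uncalled values was not part of this count. In the comparisons of labels the unblocked fit called 2 genes at day 0 and 0 at days 2 and 8. There the count mostly shows that values stayed uncalled, and it does not cover the calls of the blocked fit. No named gene called in the unblocked fit changed direction under any alternative. Some called in the blocked fit did, such as Mki67 at day 0 (0.56 without KO replicate 2) and Cd55 at day 8 (0.058 without WT replicate 3). With a mean of at least 5 TPM, 796 values were tested and all kept their call status.

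Without a block, the day 0 count of 2 became 1 with a pseudocount of 5, 1 with a mean of at least 5 TPM and 0 in a fit to only the groups compared. Without a filter, days 2 and 8 gave 3 and 6 genes, and 4 lists were called at day 0 and 11 in the interaction of day 8 with day 0. Sample quality weights gave 432, 17 and 3 genes at days 0, 2 and 8. With them 8116 genes changed between days 0 and 2 and 6342 between days 2 and 8 in WT, and 9957 and 7390 in KO. Rictor was then called at each day, with log2 differences of 0.38 (adjusted p = 0.00133), 0.61 (adjusted p = 0.000316) and 0.54 (adjusted p = 0.0292). The weights also turned the camera direction of 2 interaction lists, with medians of -0.012 for collagens and -0.009 for HOX genes. With an estimated correlation camera called 0 lists at days 0, 2 and 8 and 0 in the interaction, and 65 list calls were lost. Median-ratio scaling lost 5 list calls and quantile normalization 2, and neither turned one. Sample quality weights lost 18 list calls and gained 2. The block by day and number lost 4 and gained 3. Without the day 8 pair numbered 3, or with quality weights, that block lost 16 and gained 4 in each case.

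The block by number gave 5 genes at day 0. The block within a day gave 485, 599 and 0 genes at days 0, 2 and 8 and 16 lists at day 0, and called Rictor at day 2 (0.60, adjusted p = 0.00383). The block by day and number gave 62, 90 and 720 genes at days 0, 2 and 8, and 1 and 2 genes in the interactions of day 8 with days 2 and 0. It called Rictor at days 2 (0.60, adjusted p = 0.0194) and 8 (0.57, adjusted p = 0.00674). With this block and an estimated correlation camera called 0 lists at days 0, 2 and 8 and 0 in the interaction, and fry called 0, 2, 7 and 0.

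The same block with median-ratio scaling gave 70, 85 and 703 genes at days 0, 2 and 8, 7 and 2 in the interactions of day 8 with days 2 and 0, and called Rictor at days 2 (0.59) and 8 (0.53). The block with quantile normalization gave 67, 59 and 772, 1 gene in the interaction of day 8 with day 0, and Rictor calls at days 2 (0.61) and 8 (0.56). The block with sample quality weights gave 754, 1868 and 1528, then 28, 386 and 56 genes in the interactions of day 2 with day 0, day 8 with day 2 and day 8 with day 0. It called Rictor at each day (0.36 with adjusted p = 0.00723, 0.62 and 0.55), and the NRF2 interaction median was -0.006 with its camera direction turned. The block without the day 8 pair numbered 3 gave 765, 1277 and 680 genes, 22, 62 and 12 in the interactions and Rictor calls at each day (0.33 with adjusted p = 0.0158, 0.60 and 0.53), and turned NRF2 to 0.052. The block without the day 0 pair numbered 2 gave 16, 33 and 324 genes, 0, 0 and 0 in the interactions (403, 1413 and 1010 at an unadjusted p below 0.05), with Rictor called at days 2 (0.60) and 8 (0.57).

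Leaving out each library in turn gave 0 to 3 genes at day 0, 0 to 0 at day 2 and 0 to 1 at day 8 in limma without a block. The 0 at day 0 came without any day 0 library other than WT replicate 2, without KO replicate 2 of day 2, or without WT replicate 2 or KO replicate 1 of day 8. The 1 at day 8 came without WT replicate 2 of day 8 (Acaa1b, adjusted p = 0.00496) or without KO replicate 1 or 3 of day 0 (Acss2, adjusted p 0.0206 and 0.032). The change between days 2 and 8 in KO ranged from 2287 genes (without KO replicate 3 of day 2) to 4213 (without WT replicate 3 of day 8). Between 10 and 20 lists were called at day 0, 12 and 15 at day 2, 17 and 22 at day 8 and 16 and 24 in the interaction, and Rictor stayed between 0.26 and 0.42, 0.55 and 0.66, and 0.51 and 0.61 at days 0, 2 and 8.

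The camera direction turned for some lists when 1 library was left out, with these ranges of the median. Leaving out 1 library leaves its same-numbered partner unpaired, which the unblocked test does not allow for. At day 0 they were 0.051 to 0.33 for adipocyte identity (lowest without KO replicate 2), -0.96 to 0.49 for cell cycle (highest without KO replicate 2) and -0.14 to 0.60 for complement (lowest without WT replicate 1). At day 2 respiratory chain genes ranged from -0.215 to 0.042 (highest without KO replicate 2). At day 8 the ranges were -0.78 to 0.53 for macrophage, 0.076 to 0.35 for HOX and 0.032 to 0.71 for Wnt genes, each turned without WT replicate 3. In the interaction they were 0.007 to 0.41 for cholesterol synthesis, -0.076 to 0.39 for collagens, -0.46 to 0.076 for NRF2, -0.13 to 0.53 for HOX, 0.015 to 0.38 for TGF-beta and BMP signalling and -0.037 to 0.33 for unfolded protein response genes. Most of these turned without WT replicate 3 of day 8, the HOX list also without KO replicate 2 of day 0 and the unfolded protein response without KO replicate 3 of day 8. Among all list values with 1 library left out, 1114 were the same, 106 lost the call, 6 gained it and 16 turned.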

Other observations

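The blocked fit, the genes shared by all days and the sums per library were chosen after results were seen, and the camera tests of the lists were planned. Several genes differed between the labels in the same direction on all 3 days, from precursors to adipocytes, by amounts that were not compared between days except by the interaction tests. Hsd11b1, whose enzyme regenerates active glucocorticoid, had log2 differences of 0.87, 1.23 and 0.83 at days 0, 2 and 8. Epas1 had 0.82, 0.76 and 0.59, Pcsk6 0.78, 0.74 and 0.82, and the lipid transfer gene Pltp 0.52, 0.49 and 0.53. The small MAF genes Mafk and Maff, partners of NRF2 on DNA, had 0.39, 0.49 and 0.47, and 0.51, 0.47 and 0.45, whereas NRF2 targets as a list were not called on any day (medians 0.041, 0.044 and -0.11). In the other direction Hsd3b6 had -1.55, -1.06 and -0.77, Cpxm2 -1.14, -0.64 and -0.52, Pi15 -0.66, -0.67 and -0.81, and the plasminogen activator gene Plau -0.49, -0.50 and -0.24. These genes were singled out after their values were seen.

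The interferon response list had medians of 0.17, 0.52 and -0.52 at days 0, 2 and 8 and was called at days 2 and 8 (adjusted p = 0.468 and 0.27 with an estimated correlation). The complement list (0.24, 0.48 and 0.16) was called at day 2 alone with all libraries (adjusted p = 0.537 with an estimated correlation). At day 0 it was called higher without WT replicate 2 (0.53) or KO replicate 1 (0.60) and lower without WT replicate 1 (-0.14) or KO replicate 2 (-0.14). The differences of day 2 from the other days were not tested for lists. At day 0 the interferon medians of pairs 1, 2 and 3 were -0.031, -0.099 and 0.62, and KO library 3 of day 0 had the largest interferon sum of that day, 943.4 TPM against 532.7 to 613.3 TPM in the other 5. At day 8 the WT library numbered 3 had 1080 TPM against 374.3 to 568.6 TPM. That library and its KO partner also held the most Adgre1, a macrophage gene (763.5 and 393.6 TPM). Acta2, a myofibroblast gene, read 717 and 1431 TPM there against 4069 to 6596 TPM in the other day 8 libraries. The macrophage list is not private to macrophages in fat, and the labels name no sort that would remove such cells.

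Lists not described so far gave the following values at days 0, 2 and 8. Glucocorticoid targets (medians 0.17, 0.11 and 0.15), early adipogenic factors (0.077, -0.014 and 0.072), mural cell markers (0.22, 0.16 and 0.054), myofibroblast and SRF or YAP targets (-0.086, -0.093 and 0.22) and the mTOR complexes (0.037, -0.033 and -0.003) were not called. Insulin signalling genes were called lower at day 0 (-0.02, adjusted p = 0.0276, and adjusted p = 0.527 with an estimated correlation) and not at days 2 (0.017) and 8 (0.066). That call was lost without WT replicate 1 or 2 or KO replicate 2 or 3 of day 0 or WT replicate 3 of day 8 (adjusted p 0.0505 to 0.205). The insulin signalling medians of pairs 1, 2 and 3 at day 0 were 0.024, -0.005 and -0.04, without a common direction. Unfolded protein response genes were called lower at days 0 (-0.073, adjusted p = 0.00348) and 2 (-0.11, adjusted p = 0.0177), with adjusted p = 0.905 and 0.834 with an estimated correlation, and not at day 8 (0.039). Without WT replicate 1 or KO replicate 2 of day 0 the day 0 median was 0.036 or 0.065. At day 2 the call was lost without WT replicate 1 or 2 or KO replicate 3 (adjusted p 0.108 to 0.355). Brown and beige adipocyte genes (-0.26, adjusted p = 0.016) and pentose phosphate genes (-0.16, adjusted p = 0.0192) were called lower at day 8 and not before, and ATF4 targets again at day 8 (-0.19, adjusted p = 0.00427). With an estimated correlation those 3 gave adjusted p = 0.225, 0.456 and 0.385. Without WT replicate 2 of day 8 none of the 3 was called (adjusted p 0.14, 0.0701 and 0.13). Brown and beige genes and ATF4 targets were also lost without KO replicate 3 (adjusted p 0.0922 and 0.547), and pentose phosphate genes without WT replicate 3 (adjusted p = 0.386) or KO replicate 2 (adjusted p = 0.104). At day 2 the respiratory chain (-0.089, adjusted p = 0.000902), de novo lipogenesis (-0.14, adjusted p = 0.00436), collagens (-0.12, adjusted p = 0.0306) and Schwann cell markers (-0.27, adjusted p = 0.0151) were called lower, with adjusted p = 0.834, 0.52, 0.834 and 0.52 with an estimated correlation. Without KO replicate 2 of day 2 the respiratory median was 0.042 and de novo lipogenesis had adjusted p = 0.0504, and without WT replicate 3 the respiratory median was 0.002. The collagens were lost without WT replicate 1 or 2 or KO replicate 3 (adjusted p 0.0974 to 0.355), and Schwann cell markers without WT replicate 2 or KO replicates 1 or 3 (adjusted p 0.13 to 0.784). Matrix proteases at day 8 were called by fry in the blocked fit (median 0.28, adjusted p = 0.0155) and not by camera (adjusted p = 0.49). FOXO targets at days 0 (0.011) and 8 (0.14), and Schwann cell and endothelial markers at day 8 (-0.18 and -0.12), were not called. Epithelial, mesothelial and skeletal muscle markers kept 2, 2 and 4 members and were not tested.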
